A study of Homo sapiens with 7 samples.

How the data were processed

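Expression was profiled on Illumina HumanHT-12 bead arrays in P493-6 cells, a human B cell line in which tetracycline (Tet) represses a MYC transgene. Total RNA was made into biotinylated cRNA and hybridised to 7 arrays, 1 per sample. Per the labels, cells carried a scramble shRNA or Dpy30 shRNA #2 or #5. The labels of the 3 arrays called before Tet here do not mention Tet. Those of the other arrays place them right before Tet withdrawal, called after 3 days of Tet here, or 4 h after withdrawal. Whether both sets come from 1 experiment is not in the labels. The arrays fall in 6 groups: scramble in each of 3 states with 1 array each, knockdown before Tet with 2 (shRNA #5 and #2), and knockdown with shRNA #2 at 3 days of Tet and at 4 h with 1 each.

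The deposited table that is not normalized gives a probe intensity on a linear scale and a detection p-value for each probe and array. Per the file headers the p-value is Illumina's detection p, and its steps of 1/770 fit a rank among 770 negative-control bead types. The authors' processed values are intensity as well: each equals the signal in the other table times 1 factor per array (0.875 to 1), which sets every array median to 83.4. That scaling was found from the values, and the background treatment before it is not given in the sources used here. The table holds 26781 probes, and 845 of them are detected on no array. Depth on an array is signal over background: 70.1% to 78.2% of probes had a detection p under 0.05, and array medians lay between 83.4 and 95.4. With 1 array in 5 of the 6 groups, the number of arrays limits the precision.

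Probes were given gene symbols from the annotation table held with the data. Of the probes, 18652 had 1 symbol, 6 had several and 8123 had no gene listed, and the last 2 kinds were left out. Signals that are not normalized were background-corrected and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), with the negative-control level inferred from the detection p and an offset of 16. Probes with a detection p under 0.05 on at least 2 of 7 arrays were kept (22515, of which 16417 have 1 symbol). Where a gene had more than 1 detected probe (3267 genes), the probe with the highest mean log2 signal stood for it, which left 12198 genes.

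The effects of knockdown, of 3 days of Tet and of Tet removal came from an additive limma fit of Tet state and knockdown (7 arrays, 3 residual degrees of freedom). Its residual holds the difference between the shRNAs and any interaction of state and knockdown. Knockdown before Tet and the differences in response came from a fit with 1 mean for each of the 6 groups (1 residual degree of freedom, from shRNA #2 against #5), in which every other array is assumed to vary like that pair. In that fit knockdown before Tet is the mean of both shRNAs, also for the response to Tet, whereas slopes and list medians by pair use shRNA #2 alone. Tests were two-sided with empirical Bayes variances, and Benjamini-Hochberg adjusted p under 0.05 was called passed. On simulated data with 200 changed genes among 12198, 4.43% to 5.60% of calls of the additive fit were false, and it found 79.5% (knockdown), 56.9% (Tet) and 39.8% (removal) of genes changed 2-fold. The simulated noise was independent between arrays and genes, with spreads drawn from the fitted prior. These rates thus need not hold for the measured arrays.

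The comparisons, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. DPY30 and MYC are always named. For each comparison the rule takes the 10 largest rises and the 10 largest falls among genes that passed and moved the same way in every pair of arrays, and, where fewer than 10 pass in a direction, up to 5 of the largest that did not pass. From each list described it takes up to 4 members of largest change, those that passed first. A fold is written as "at least" where the gene is undetected on all arrays of 1 side, and is then taken against the lowest detected signal.

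The 28 gene lists cover complexes, pathways and markers of other cell types. They were tested against all other genes with camera for the 3 additive comparisons, with an inter-gene correlation preset at 0.01. Beside it the correlation was estimated, and each set was adjusted over 84 tests. With the preset, camera takes its degrees of freedom from the number of genes. With the estimate it takes the 3 residual degrees of freedom of the arrays, so few lists could pass. A list is said to be called where its adjusted p with the preset correlation is under 0.05. For the other contrasts a list's median was set against 10000 random lists matched on size and mean signal, as a description. Members of a list can move together, which genes drawn singly do not, so such a rank is not a p-value. Counts adjusted over the list alone use Benjamini-Hochberg over its members. The size of a response was the slope through 0 of the shRNA #2 change on the scramble change by total least squares (slope 0.803 recovered on simulated data made with a smaller response in knockdown). Effects of the shared scramble array on the correlation of the shRNAs came from 100 simulations.

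Alternatives were quantile normalization without background correction, the authors' median-scaled values, background correction with equal medians, no filter on detection, detection p under 0.01 on all arrays, each probe tested by itself, an intensity trend with robust variance, a fit of 6 arrays without shRNA #5, a cell-means fit, and leaving out each array. Equal medians for the list tests were chosen after seeing the data. Every normalization moved the median of all genes by less than 0.1 log2. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. No genome was used.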

Results

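Gene expression was measured on 7 Illumina HumanHT-12 arrays in P493-6 cells, an established human B cell line immortalised with Epstein-Barr virus in which tetracycline (Tet) switches off a MYC transgene. The cells carried a scramble control shRNA or 1 of 2 shRNAs, #2 and #5, against DPY30, a core subunit of the SET1/MLL complexes that methylate histone H3 at lysine 4. RNA was taken before Tet (labels with no mention of Tet), after 3 days of Tet (Myc off), and 4 h after Tet was washed away (Myc back on). Scramble cells gave 1 array in each state. Knockdown cells gave 2 arrays before Tet, 1 for each shRNA, and 1 array of shRNA #2 in each later state. No group holds 2 arrays of the same cells and treatment, and nothing in the labels says that the arrays are separate cultures. The p-value of a gene thus measures only the spread between these arrays. With the preset correlation, the p-value of a list measures the spread across genes, however small it is, and not the spread between arrays or cultures. Between 70.1% and 78.2% of the 26781 probes were detected on each array, and the median probe signal lay between 83.4 and 95.4 units. The number of arrays limits the precision of every value. Over the 12198 genes tested, the first principal component held 62.6% of the variance and parted the 3 arrays before Tet (-53.9 to -46.6) from the 4 later ones (29.2 to 50.3).

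DPY30 transcript was reduced in every knockdown array, the check on which the other comparisons rest. With probe ILMN_2131880, DPY30 signal before Tet was 15.1% of the scramble level with shRNA #5 and 21.3% with shRNA #2. With shRNA #2 it was 15.4% of the scramble level after 3 days of Tet and 15.9% at 4 h after removal. Over the 3 states DPY30 fell by 2.60 on the log2 scale (SE 0.16, 4 knockdown against 3 scramble arrays, limma adjusted p = 0.00164). This call too was lost without either array of 3 days of Tet. The other DPY30 probe, ILMN_2131882, averaged 62.1% of scramble and was detected on 2 of the 7 arrays. MYC (probe ILMN_1680618), the gene under Tet control, dropped after 3 days of Tet to 7.63% of its earlier signal in scramble cells and 11.4% in shRNA #2 cells. The second MYC probe, ILMN_2110908, gave 5.29% and 7.12%. In the 4 h after Tet removal MYC rose 16.8-fold in scramble and 11.4-fold in shRNA #2 cells, to 128% and 129% of the level before Tet. With the authors' median-scaled values those levels were 103% and 104%, so a return above the level before Tet depends on the normalization. The second probe gave 22.9-fold and 18.7-fold. After 3 days of Tet, MYC signal in shRNA #2 cells was 165% of that in scramble cells, against 111% at 4 h and 111% (#2) and 113% (#5) before Tet. With the second probe these were 160% after 3 days, 130% at 4 h, and 119% (#2) and 115% (#5) before Tet. After 3 days the authors' median-scaled values gave 146% and, with the second probe, 143%. The MYC difference between knockdown and scramble did not pass over the 3 states (0.33, SE 0.15, adjusted p = 0.249), nor did the difference in its response to Tet (0.56, SE 0.33, adjusted p = 0.976). DPY30 itself fell with Tet, by 0.71 (SE 0.19, adjusted p = 0.0141). That call was lost without the scramble array of 3 days of Tet (-0.77, adjusted p = 0.0676) or without the shRNA #2 array of 3 days (-0.63, adjusted p = 0.146). At 4 h DPY30 stood at 98.3% of its 3-day level in scramble cells and 102% in shRNA #2 cells.

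**Figure D1:**
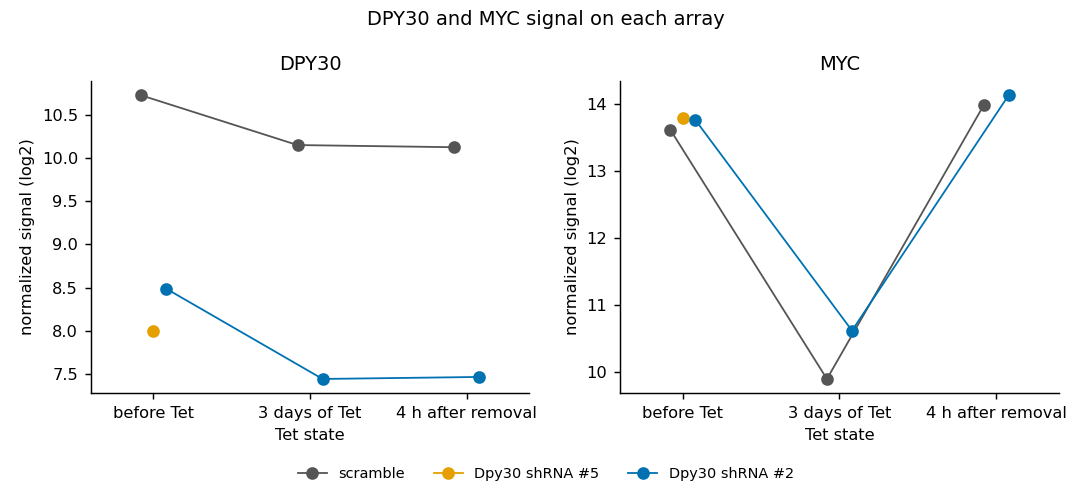
Normalized signal (log2) of DPY30 and MYC on each of the 7 arrays by Tet state, 1 point per array, with lines joining arrays of the same shRNA. DPY30 lies at 10.1 to 10.7 in scramble and 7.44 to 8.49 in knockdown arrays, and MYC drops from 13.6 to 9.90 in scramble and from 13.8 to 10.6 in shRNA #2 cells after 3 days of Tet, and stands at 14.0 and 14.1 at 4 h after removal.

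The first state comparison asks what changed over 3 days of Tet, which turned Myc off. Effects of Tet itself, or of a separate experiment before Tet, cannot be told apart from those of Myc. The largest falls were in NPW, which encodes neuropeptide W (-5.35 (SE 0.22) log2), GALNT18 (-4.37 (SE 0.19)), and CBS, the enzyme that makes cystathionine (-4.18 (SE 0.34)). KISS1R, the kisspeptin receptor, was detected on all 3 arrays before Tet and neither array after it, a fall of at least 24.0-fold. The amino acid transporter SLC7A2 (-4.11), DDN (-4.04), CTXN1 (-4.03), the fatty acid binding protein FABP5 (-3.85), the creatine kinase CKB (-3.73) and BZW2 (-3.72) also fell. NPW, GALNT18, SLC7A2 and DDN were detected on 1 of the 2 arrays of 3 days each, so the size of their falls is set by signal near background. The largest rises were in the leukocyte integrin chains ITGAM (3.83 (SE 0.22)) and ITGAX (3.71 (SE 0.17)), the ceramide kinase CERK (3.72 (SE 0.29)) and the cytokine TNF (3.70 (SE 0.17)). They were followed by BASP1 (3.45), the adhesion molecule CEACAM1 (3.40), CUEDC1 (3.32), the activation marker CD69 (3.30), ANXA1 (3.25) and the interferon-induced OAS3 (3.25). ITGAX was detected on 2 of the 3 arrays before Tet. In limma 5807 of 12198 genes passed, 3198 higher and 2609 lower (2 arrays at 3 days against 3 before Tet). The 20 genes named here moved the same way in scramble and shRNA #2 cells, with adjusted p from 2.75e-05 to 0.000296. Without the scramble array of 3 days 3440 genes passed, and without the shRNA #2 array of 3 days 3592.

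The lists of this paragraph, on growth and biosynthesis, were called with negative medians with Myc off. Of 46 classical Myc targets, 42 fell (43 adjusted over the list alone), among them SRM (-2.83), RRP9 (-2.81), NME1 (-2.62) and CDC25A (-2.60). The median change of that list was -1.76 (adjusted p = 5.31e-19, and adjusted p = 0.386 with an estimated correlation). Of 53 ribosome biogenesis genes, 50 fell and 1 rose (50 and 1 adjusted over the list alone), including MYBBP1A (-2.68) and RRP12 (-2.66) and NLE1, which was at least 6.71-fold lower. MYBBP1A was detected on 1 of the 2 arrays of 3 days. The median of the ribosome biogenesis list was -1.57 (adjusted p = 2.51e-20, and adjusted p = 0.41 with an estimated correlation). All 25 nucleotide and one-carbon synthesis genes fell, 25 also when adjusted over the list alone, led by MTHFD1L (-3.46), PAICS (-3.14), PFAS (-2.97) and PPAT (-2.68). Their median was -1.69 (adjusted p = 2.8e-14, and adjusted p = 0.378 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes, 49 fell (52 adjusted over the list alone), such as MRPL4 (-2.13) and MRPS2 (-2.03). Their median was -0.83 (adjusted p = 9.17e-14, and adjusted p = 0.41 with an estimated correlation). Of 18 cytoplasmic tRNA synthetase genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone), such as VARS1 (-2.50) and IARS1 (-2.0). Their median was -0.85 (adjusted p = 5.42e-05, and adjusted p = 0.41 with an estimated correlation). Of 35 translation factor genes, 23 fell (26 adjusted over the list alone), such as EIF2B3 (-1.64) and EIF3C (-1.42). Their median was -0.59 (adjusted p = 3.28e-07, and adjusted p = 0.386 with an estimated correlation). Of 38 cytoplasmic ribosomal protein genes, 12 fell (12 adjusted over the list alone), such as RPS21 (-2.48) and RPL14 (-2.45). Their median was -0.19 (adjusted p = 0.00093, and adjusted p = 0.446 with an estimated correlation). Under the authors' values that median was -0.36, and with equal medians -0.43. Of 25 heat shock and chaperone genes, 16 fell (16 adjusted over the list alone), such as FKBP4 (-3.01), HSPE1 (-1.76) and HSPD1 (-1.73). Their median was -0.94 (adjusted p = 6.02e-05, and adjusted p = 0.506 with an estimated correlation).

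Lists of energy, sterol, stress and cell cycle genes were also called with negative medians after 3 days of Tet. Of 57 nuclear-encoded oxidative phosphorylation genes, 32 fell (33 adjusted over the list alone), such as CYC1 (-1.37) and NDUFA10 (-1.28). Their median was -0.56 (adjusted p = 3.8e-08, and adjusted p = 0.455 with an estimated correlation). In glycolysis and lactate export 11 fell and 2 rose (12 and 2 adjusted over the list alone) of 17 genes, with falls in LDHB (-2.06), GPI (-2.04) and HK2 (-1.69). Their median was -0.88 (adjusted p = 0.000577, and adjusted p = 0.446 with an estimated correlation). Cholesterol synthesis had 16 measured genes, of which 7 fell (7 adjusted over the list alone), such as DHCR7 (-1.90), EBP (-1.04) and CYP51A1 (-1.01). Their median was -0.68 (adjusted p = 0.00314, and adjusted p = 0.586 with an estimated correlation). Among ATF4 and unfolded protein response genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone) of 25, with falls in the serine synthesis enzymes PSAT1 (-3.64) and PHGDH (-2.64) and in STC2 (-3.29) and SLC7A5 (-3.25). Their median was -0.71 (adjusted p = 0.00596, and adjusted p = 0.506 with an estimated correlation). Without the scramble array before Tet it was -0.41. STC2 was detected on 1 of the 2 arrays of 3 days. Of 33 DNA replication genes, 29 fell and 1 rose (30 and 1 adjusted over the list alone), such as UHRF1 (-2.53), GINS2 (-2.53), POLE2 (-2.52) and MCM4 (-2.37). Their median was -1.20 (adjusted p = 1.43e-11, and adjusted p = 0.388 with an estimated correlation). Of 32 mitosis genes, 31 fell (32 adjusted over the list alone), such as CDC20 (-2.30), BIRC5 (-2.13), AURKB (-2.10) and CCNA2 (-2.06). Their median was -1.52 (adjusted p = 2.03e-13, and adjusted p = 0.41 with an estimated correlation). CDC20 missed the threshold without the shRNA #2 array of 3 days (-1.80, adjusted p = 0.0507).

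The lists of this paragraph were called with positive medians with Myc off. Of 29 interferon response genes, 28 rose (29 adjusted over the list alone), such as OAS3 (3.25), SAMD9L (2.95), IFI35 (2.89) and IFI27 (2.84). Their median was 1.71 (adjusted p = 3.16e-12, and adjusted p = 0.389 with an estimated correlation). Of 21 MHC and antigen presentation genes, 20 rose (20 adjusted over the list alone), such as HLA-DMB (2.29), HLA-DOB (2.28) and HLA-E (2.12). Their median was 1.44 (adjusted p = 6.99e-09, and adjusted p = 0.41 with an estimated correlation). Of 27 NF-kB targets, 22 rose (24 adjusted over the list alone), such as the cytokines TNF (3.70), LTB (2.79) and LTA (2.21). Their median was 1.54 (adjusted p = 2.57e-08, and adjusted p = 0.386 with an estimated correlation). Of 19 B cell identity genes, 15 rose (17 adjusted over the list alone), such as VPREB3 (1.97) and CD72 (1.94) and MS4A1, which encodes CD20 (1.90). Their median was 1.43 (adjusted p = 2.03e-05, and adjusted p = 0.386 with an estimated correlation). Of 20 immediate early genes, 16 rose (16 adjusted over the list alone), such as DUSP5 (2.81), JUN (2.4) and EGR1 (1.83). Their median was 1.36 (adjusted p = 2.03e-05, and adjusted p = 0.41 with an estimated correlation). Of 35 lysosome and autophagy genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), such as CTSZ (1.98), NPC2 (1.65) and CTSB (1.58). Their median was 0.73 (adjusted p = 0.000594, and adjusted p = 0.41 with an estimated correlation). Of 24 p53 targets and CDK inhibitors, 16 rose (16 adjusted over the list alone), such as CDKN2D (1.73), TP53I3 (1.29) and XPC (1.21). Their median was 0.71 (adjusted p = 0.00021, and adjusted p = 0.446 with an estimated correlation). Of 9 markers of monocytes and macrophages, 6 rose (6 adjusted over the list alone), among them ITGAM (3.83), LYZ (2.52) and CD68 (2.35). Their median was 1.23 (adjusted p = 0.0168, and adjusted p = 0.446 with an estimated correlation). With no filter on detection the monocyte list lost its call (median 0.81, adjusted p = 0.0602).

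The other 6 lists were not called with Myc off. In the SET1/MLL complex list 6 rose and 4 fell (6 and 4 adjusted over the list alone) of 20 (adjusted p = 0.901): the WD-repeat core subunit WDR5 (-1.31), PAXIP1 (-1.25) and BOD1 (-1.22) fell and the demethylase KDM6A (1.10) rose. In the MYC network list 4 rose and 2 fell (5 and 2 adjusted over the list alone) of 11 (adjusted p = 0.523), and the MYC antagonists MXD3 (1.54), MXD1 (1.16) and MXD4 (1.11) were among those that rose. Polyamine synthesis genes went both ways, and of 10, 4 fell and 2 rose (4 and 2 adjusted over the list alone) (adjusted p = 0.531): SRM (-2.83), ODC1 (-1.93) and SMS (-1.57) fell and the catabolic enzyme SAT1 (2.04) rose. Of 12 plasma cell genes, 5 fell (5 adjusted over the list alone) (adjusted p = 0.0717), such as FKBP11 (-2.64), MZB1 (-1.43) and XBP1 (-1.34). Markers of T and NK cells were split: 4 rose and 1 fell (4 and 1 adjusted over the list alone) of 10 (adjusted p = 0.532), with the largest rise in CD2 (1.61). Of 7 fibroblast and epithelial markers, 1 fell (1 adjusted over the list alone) (adjusted p = 0.904), which was EPCAM (-1.47). Across the 3 comparisons tested with camera, 47 of 84 list tests passed with a correlation preset at 0.01. With the correlation estimated from the arrays 0 passed, and the smallest adjusted p was 0.378. That version also has 3 residual degrees of freedom in place of the number of genes, so its 0 cannot be credited to correlation alone. The list with that smallest value, nucleotide synthesis with Myc off, had an estimated correlation of 0.013, close to the preset.

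**Figure D2:**
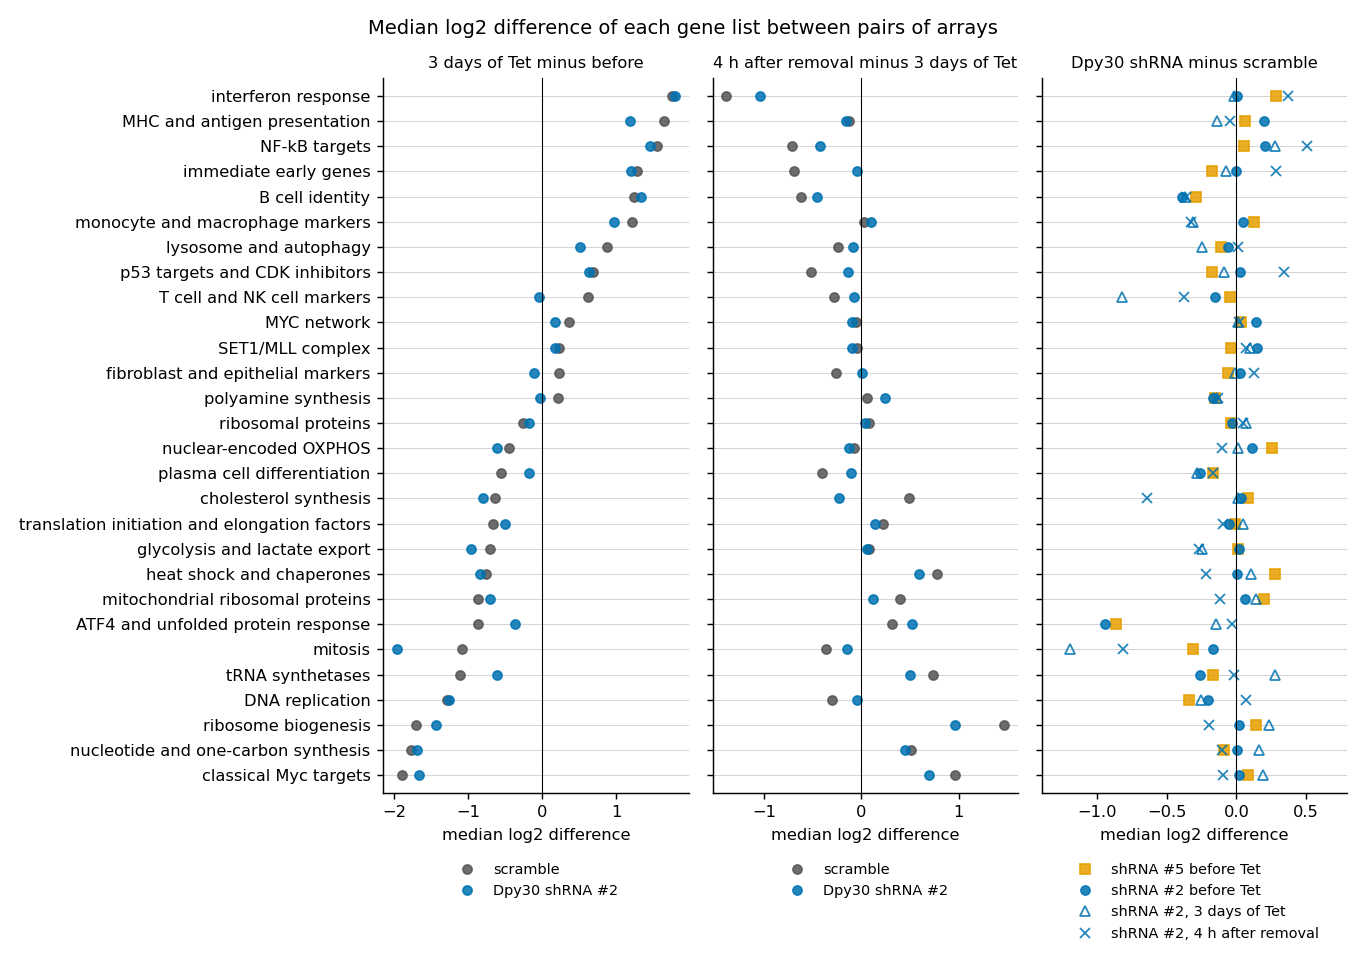
Median log2 difference of the members of each of the 28 gene lists between pairs of arrays, 1 symbol per pair: 3 days of Tet minus before and 4 h after removal minus 3 days (grey scramble, blue shRNA #2), and knockdown minus scramble in each state (square shRNA #5, other symbols shRNA #2). Interferon genes lie at 1.75 and 1.79 with Tet and -1.39 and -1.04 on its removal, and ribosome biogenesis genes at -1.71 and -1.43 and then 1.47 and 0.97.

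The next comparison asks what changed within 4 h of Tet removal, when Myc came back. Removal of Tet and the return of Myc came together, so their effects cannot be told apart here. ADAMTSL2 rose most (5.07 (SE 0.29) log2, against signal near background, since it was detected on 1 of the 2 arrays of 3 days), followed by MYC itself (3.79 (SE 0.19)), SAMSN1 (3.36 (SE 0.31)) and CDH1, the gene of E-cadherin, which was detected on both arrays at 4 h and neither at 3 days and was at least 7.24-fold higher. The MIR181A2HG transcript (3.06), the chloride channel gene CLIC3 (3.03), the tRNA methyltransferase METTL1 (3.00), the mitochondrial folate enzyme MTHFD1L (3.00), BZW2 (2.93) and the glycosyltransferase A4GALT (2.88) also rose. Several of these genes rose above their level before Tet. ADAMTSL2 stood at 4.48 to 4.78 before Tet and at 9.38 and 10.22 at 4 h. CDH1 stood at 4.32 to 4.49 and then at 7.64 and 7.59. SAMSN1, MIR181A2HG, CLIC3 and A4GALT also lay well above their level before Tet, whereas METTL1, MTHFD1L and BZW2 came back near or below theirs. The receptor gene GPR18 (-2.81 (SE 0.39)), the B cell transcription factor EBF1 (-2.61 (SE 0.25)), CEACAM1 (-2.17), SAMD9L (-2.12), SERPINI1 (-2.11) and the cell cycle factor E2F2 (-2.11) fell most, with STK3 (-2.10), ANTXR2 (-2.10), TMEM71 (-2.07) and the adenosine receptor ADORA2A (-2.05). In limma 1857 genes passed, 967 higher and 890 lower (2 arrays against 2), and the 20 named genes moved the same way in both cell populations with adjusted p from 0.000224 to 0.00605. The count rests on single arrays: it was 185 without the scramble array of 3 days of Tet, 582 without the shRNA #2 array of 3 days, 482 without the scramble array of 4 h and 739 without the shRNA #2 array of 4 h.

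The lists of this paragraph were called with positive medians on Tet removal. Of 53 ribosome biogenesis genes, 43 rose (46 adjusted over the list alone), led by NOP16 (2.30), RRS1 (2.26), WDR12 (2.20) and RRP12 (2.17). Their median was 1.22 (adjusted p = 2.4e-27, and adjusted p = 0.388 with an estimated correlation). Of 46 classical Myc targets, 26 rose and 3 fell (30 and 3 adjusted over the list alone), with rises in PPRC1 (2.09) and RRP9 (2.01), a fall in E2F2. Their median was 0.77 (adjusted p = 1.06e-12, and adjusted p = 0.388 with an estimated correlation). Of 25 nucleotide and one-carbon synthesis genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with rises in PPAT (2.51), PAICS (2.27) and NME1 (1.67). Their median was 0.58 (adjusted p = 5.71e-05, and adjusted p = 0.386 with an estimated correlation). Of 18 tRNA synthetase genes, 5 rose (10 rose and 1 fell adjusted over the list alone), such as YARS1 (1.2) and IARS1 (1.08). Their median was 0.68 (adjusted p = 0.000352, and adjusted p = 0.446 with an estimated correlation). Of 25 heat shock and chaperone genes, 13 rose (16 rose and 1 fell adjusted over the list alone), such as FKBP4 (1.35), CCT5 (1.35) and HSPD1 (1.15). Their median was 0.59 (adjusted p = 4.48e-08, and adjusted p = 0.417 with an estimated correlation). Of 35 translation factor genes, 6 rose (7 adjusted over the list alone), such as EIF5B (0.95) and EIF2S2 (0.86). Their median was 0.20 (adjusted p = 0.00122, and adjusted p = 0.389 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes, 15 rose (19 adjusted over the list alone), such as MRPL4 (1.42) and MRPS17 (1.35). Their median was 0.25 (adjusted p = 0.000234, and adjusted p = 0.676 with an estimated correlation), and without the scramble array of 4 h that call was lost (median 0.079, adjusted p = 0.0595). That median was 0.38 without the shRNA #2 array of 4 h. The tRNA synthetase median was 0.40 without the scramble array of 3 days, and the nucleotide synthesis median 0.33 after quantile normalization without background correction.

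The lists of this paragraph were called with negative medians on Tet removal. Of 29 interferon response genes, 23 fell (25 adjusted over the list alone), such as SAMD9L (-2.12), IFIT3 (-1.95) and IFIT1 (-1.89). Their median was -1.20 (adjusted p = 1.46e-16, and adjusted p = 0.388 with an estimated correlation). Of 19 B cell identity genes, 5 fell (9 adjusted over the list alone), such as EBF1 (-2.61), CD72 (-1.68) and TCL1A (-1.52). Their median was -0.56 (adjusted p = 0.000134, and adjusted p = 0.386 with an estimated correlation). Of 27 NF-kB targets, 7 fell (15 fell and 1 rose adjusted over the list alone), such as CCL3 (-2.03), TNF (-1.38) and LTB (-1.24). Their median was -0.59 (adjusted p = 0.00176, and adjusted p = 0.41 with an estimated correlation). Of 21 MHC and antigen presentation genes, 4 fell (4 adjusted over the list alone), such as TAP1 (-1.30) and PSMB9 (-0.95). Their median was -0.14 (adjusted p = 0.0284, and adjusted p = 0.676 with an estimated correlation). Without the scramble array of 3 days (median -0.13, adjusted p = 0.16) or the shRNA #2 array of 4 h (-0.11, adjusted p = 0.115) the MHC list was not called. Without the scramble array of 4 h its median was -0.235. Of 24 p53 targets and CDK inhibitors, 4 fell (6 adjusted over the list alone), such as CDKN2D (-1.92) and DDB2 (-1.23). Their median was -0.34 (adjusted p = 0.00627, and adjusted p = 0.586 with an estimated correlation), a call lost without the scramble array of 4 h (-0.26, adjusted p = 0.202).

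A further 3 lists were called on Tet removal with calls that single arrays changed, 2 of them also lost with the processing. Of 25 ATF4 and unfolded protein response genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with rises in the amino acid transporter subunits SLC7A5 (2.46) and SLC3A2 (1.61) and a fall in DDIT4 (-1.38). Their median was 0.40 (adjusted p = 0.00654, and adjusted p = 0.506 with an estimated correlation). That median was -0.027 without the shRNA #2 array of 4 h (adjusted p = 0.355), 0.21 without the scramble array of 3 days (adjusted p = 0.0853) and 0.655 without the scramble array of 4 h. Of the 10 genes of the polyamine synthesis list, 4 rose (4 adjusted over the list alone). They were ODC1 (1.90), SRM (1.90), AMD1 (1.01) and the catabolic enzyme SMOX (1.65), where SMOX was detected on 1 of the 2 arrays of 3 days. The median of the 10 was 0.11 (adjusted p = 0.0473, and adjusted p = 0.41 with an estimated correlation). The polyamine median was -0.055 without the shRNA #2 array of 3 days (adjusted p = 0.0418) and 0.28 without the scramble array of 3 days (adjusted p = 0.0193), and 0.23 without the shRNA #2 array of 4 h (adjusted p = 0.0226). Without any other array the polyamine list was not called, with adjusted p from 0.0563 to 0.0658, nor was it after quantile normalization without background correction (0.10, adjusted p = 0.065), with the authors' values (0.067, adjusted p = 0.0601) or with detection at p under 0.01 on all arrays (0.024, adjusted p = 0.19). With equal medians it was 0.060. Of 33 DNA replication genes, 4 fell (4 adjusted over the list alone), such as CDT1 (-1.43, detected on 1 of the 2 arrays of 4 h). Their median was -0.15 (adjusted p = 0.0491, and adjusted p = 0.676 with an estimated correlation). The replication call was lost without any 1 of 5 arrays, with adjusted p from 0.0539 without the scramble array before Tet to 0.607 without the scramble array of 4 h (median -0.0815). The replication median was -0.30 without the shRNA #2 array of 3 days and -0.35 without the shRNA #2 array of 4 h. The replication list was not called under the same 3 settings as the polyamine list (adjusted p = 0.075, 0.0634 and 0.229). The other 13 lists were not called, with adjusted p from 0.0663 for immediate early genes, of which 5 fell (7 adjusted over the list alone) of 20, to 0.914 for fibroblast and epithelial markers. Mitosis genes (adjusted p = 0.148) and ribosomal protein genes (adjusted p = 0.367) were among them.

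Most genes that rose on Tet removal had fallen with Tet. Of the 967 genes that rose at 4 h, 638 (66.0%) had fallen with Tet, against 207 if the calls were independent, and these 638 are a minority of the 2609 that had fallen. Of the 890 that fell, 589 (66.2%) had risen with Tet, against 233 if independent. Both contrasts share the arrays of 3 days of Tet. For that reason alone simulated arrays with no effect gave r -0.50 between the 2 mean changes across genes, where the measured r was -0.475, and a covariance of -0.023, where the measured one was -0.229. Between cell populations, with no array shared, the correlation across genes was -0.36 (Tet response of scramble against removal response of shRNA #2) and -0.45 (the reverse), where genes are not independent replicates.

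The knockdown comparison asks what differed between knockdown and scramble cells across the 3 Tet states. Of its 4 pairs of arrays, 1 is of shRNA #5 and the others are of shRNA #2 in successive states. Effects particular to the shRNA #2 cells thus cannot be set apart from loss of DPY30. Beside DPY30, the largest falls were in the growth factor receptor PDGFRB (-2.48 (SE 0.23) log2), the claudin CLDN23 (-1.99 (SE 0.29)), the galectin LGALS2 (-1.93 (SE 0.21)), FCER1G, the common gamma chain of Fc receptors (-1.90 (SE 0.25)), and the chemokine receptor CX3CR1 (-1.90 (SE 0.25)). CAMP, the cathelicidin gene (-1.86), and the lipid-presenting CD1D (-1.69) fell too and were detected on 2 of the 4 knockdown arrays each. The readthrough symbol BORCS8-MEF2B (-1.85) and the intermediate filament gene NES (-1.71) complete the falls. The largest rises were in the proteoglycan gene SPOCK2 (1.92 (SE 0.34)), ANXA1 (1.53 (SE 0.18)), the DNA sensor AIM2 (1.46 (SE 0.15)), CRIP2 (1.45 (SE 0.20)) and the histone gene H2BC21 (1.44 (SE 0.17)). The prostaglandin receptor PTGER4 (1.43), the lysosomal membrane protein SCARB2 (1.43), the phosphodiesterase PDE7B (1.41), the sphingosine phosphate receptor S1PR1 (1.27) and C12orf76 (1.24) also rose. PDE7B was detected on 2 of the 3 scramble arrays. In limma 273 of 12198 genes passed, 125 higher and 148 lower (4 arrays against 3), and each named gene moved the same way in all 4 pairs of arrays, with adjusted p from 0.00164 to 0.0493. At an unadjusted p under 0.05 there were 2692 genes, where 610 would come by chance. The count depends on which arrays are used. Leaving out 1 gave 0 (either array of 3 days of Tet), 1 (either array of 4 h), 6 (shRNA #2 before Tet), 561 (scramble before Tet) or 668 (shRNA #5). Beside the 0, limma had 1525 genes at an unadjusted p under 0.05. Without either array of 3 days, or of 4 h, that whole state leaves the knockdown estimate, because its other array is fitted by the state alone. Leaving out either array of such a state is thus the same test. Without the scramble array before Tet, the state before Tet leaves the estimate likewise. The count also depends on the processing, with 163 genes after quantile normalization without background correction, 99 with the authors' median-scaled values, 459 with an intensity trend and robust variance, and 129 in a cell-means fit.

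**Figure D3:**
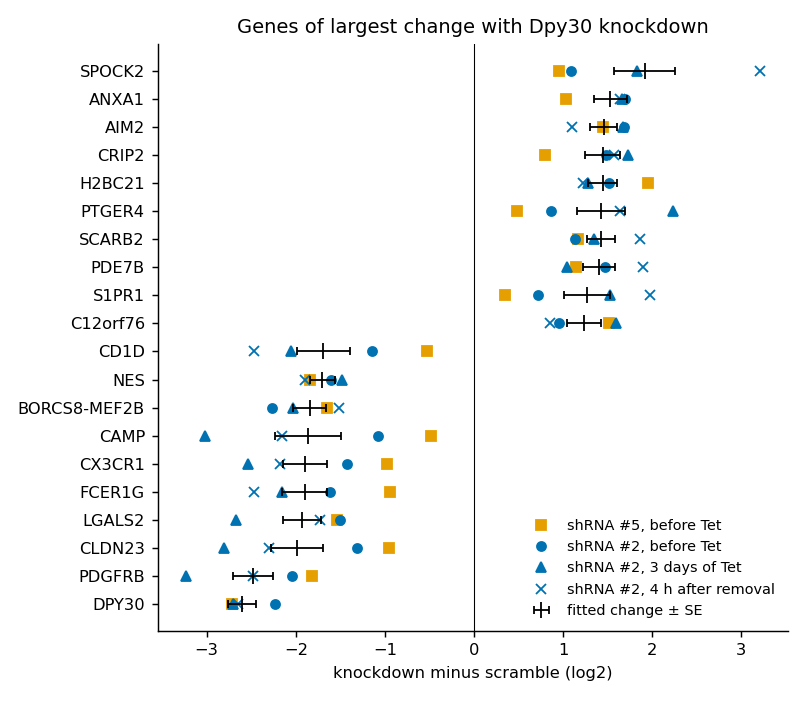
Log2 difference between Dpy30 knockdown and scramble for the 20 genes of largest change that passed, 1 symbol per pair of arrays, with the fitted change and its standard error as a bar. All 4 pairs lie on the same side of 0 for each gene, from -2.60 for DPY30 to 1.92 for SPOCK2.

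Mitosis genes had the called list median furthest from 0 with knockdown. All 32 had negative changes, 3 passed over all genes and 27 adjusted over the list alone, and the median was -0.65 (adjusted p = 3.23e-15, and adjusted p = 0.41 with an estimated correlation). HMMR (-1.09), the survivin gene BIRC5 (-1.07) and PRC1 (-0.93) passed. By pair, the median of the mitosis list was -0.31 for shRNA #5 and -0.17 for shRNA #2 before Tet, -1.20 after 3 days of Tet and -0.81 at 4 h. Of 33 DNA replication genes 0 passed in limma (7 at an unadjusted p under 0.05) and 4 fell adjusted over the list alone. Their median was -0.17 (adjusted p = 0.00122, and adjusted p = 0.477 with an estimated correlation). Of 19 B cell identity genes, 3 fell (8 adjusted over the list alone), namely the coreceptor CD72 (-1.61), VPREB3 (-1.46) and the coactivator POU2AF1 (-0.80). Their median was -0.23 (adjusted p = 0.00044, and adjusted p = 0.388 with an estimated correlation). Of 12 plasma cell genes 0 passed in limma (5 at an unadjusted p under 0.05) and 2 fell adjusted over the list alone. Their median was -0.28 (adjusted p = 0.00987, and adjusted p = 0.388 with an estimated correlation). Of 10 T and NK cell markers, 3 fell (5 adjusted over the list alone), namely the perforin gene PRF1 (-1.15), CD7 (-0.84) and NKG7 (-0.68), where CD7 was detected on 3 of the 4 knockdown arrays. Their median was -0.63 (adjusted p = 0.000349, and adjusted p = 0.389 with an estimated correlation). Without the scramble array before Tet the replication list (median -0.15, adjusted p = 0.0899) and the plasma cell list (-0.21, adjusted p = 0.063) were not called. Leaving out 1 array moved 3 medians by over 1.5 times with the call kept: replication to -0.25 without either array of 4 h, and B cell identity to -0.39 and T and NK markers to -0.35 without either array of 3 days of Tet. Quantile normalization without background correction gave -0.29 and the authors' values -0.38 for the T and NK markers, and genes detected at p under 0.01 on all arrays -0.39 for B cell identity.

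Of 25 ATF4 and unfolded protein response genes, 1 fell (3 adjusted over the list alone) with knockdown, the lipoprotein receptor VLDLR (-1.60, detected on 3 of the 4 knockdown arrays), and the median was -0.47 (adjusted p = 2.88e-05, and adjusted p = 0.41 with an estimated correlation). Without the scramble array before Tet that median was -0.14 (adjusted p = 0.199). Of 27 NF-kB targets 3 rose and 1 fell (9 and 3 adjusted over the list alone). Their median was 0.30 (adjusted p = 0.00455, and adjusted p = 0.41 with an estimated correlation). The chemokine CXCL10 (1.06), TNFAIP2 (1.02) and the feedback inhibitor TNFAIP3 (0.97) rose and the cytokine subunit EBI3 (-1.29) fell, and with genes detected at p under 0.01 on all arrays the list was not called (0.27, adjusted p = 0.236). TNFAIP2 and TNFAIP3 were detected on 2 of the 3 scramble arrays each. Of 17 glycolysis genes, 1 fell (2 adjusted over the list alone), the hexokinase HK2 (-1.22). Their median was -0.15 (adjusted p = 0.0143, and adjusted p = 0.586 with an estimated correlation), not called without either array of 3 days of Tet (-0.064, adjusted p = 0.0749 and 0.0648) or of 4 h (-0.10, adjusted p = 0.0752). Glycolysis had a median of -0.26 without the scramble array before Tet and -0.27 with equal medians, and NF-kB targets one of 0.46 without that array. Of 29 interferon genes 0 passed in limma (9 at an unadjusted p under 0.05; 0 adjusted over the list alone). Their median was 0.24 (adjusted p = 0.0363, and adjusted p = 0.676 with an estimated correlation). The interferon call was lost with the authors' median-scaled values (0.16, adjusted p = 0.0931), with equal medians (0.15, adjusted p = 0.104), with detection at p under 0.01 on all arrays (0.25, adjusted p = 0.0519), and without the scramble (0.17, adjusted p = 0.122) or shRNA #5 array before Tet (0.14, adjusted p = 0.141) or either array of 4 h (0.15, adjusted p = 0.352 and 0.355). Of 35 lysosome genes 0 passed in limma (10 at an unadjusted p under 0.05; 0 adjusted over the list alone). Their median was -0.081 (adjusted p = 0.0473, and adjusted p = 0.562 with an estimated correlation), not called without shRNA #5 (-0.0635, adjusted p = 0.0798) or either array of 3 days (-0.058, adjusted p = 0.333 and 0.296).

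Classical Myc targets and ribosome genes were not called for knockdown over the 3 states. Of 46 Myc targets, 1 fell (2 adjusted over the list alone), E2F2 (-0.94), with a median of 0.0034 (adjusted p = 0.978). Of 53 ribosome biogenesis genes 0 passed in limma (0 at an unadjusted p under 0.05; 0 adjusted over the list alone), with adjusted p = 0.624 for the list. In the SET1/MLL complex list DPY30 alone of 20 members passed (adjusted p = 0.766 for the list). Single members of other lists passed: the thymidine kinase TK1 (-1.13), the macrophage marker CD68 (-1.16) and the co-chaperone DNAJB6 (0.68). The 18 lists not called had adjusted p from 0.161 to 0.978. This comparison averages over the states, and the median of shRNA #2 minus scramble was 0.24 after 3 days of Tet (43 of 53 genes higher) and -0.20 at 4 h (43 of 53 lower) for ribosome biogenesis genes, and 0.19 and -0.099 for classical Myc targets.

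Before Tet, 2 knockdown arrays were compared with 1 scramble array, and 0 genes passed in limma (898 at an unadjusted p under 0.05, where 610 would come by chance; smallest adjusted p 0.314). The largest differences that did not pass were INHBE, an activin subunit gene (-4.14 (SE 0.79) log2, adjusted p = 0.563), ASS1, the argininosuccinate synthase gene (-2.60 (SE 0.24), adjusted p = 0.314), VLDLR (-2.57 (SE 0.27), detected on 1 of the 2 knockdown arrays), PSAT1 (-2.49 (SE 0.31)) and DPY30 (-2.48 (SE 0.28)). On the higher side were the metallothionein gene MT1G (at least 3.44-fold, adjusted p = 0.777), RN7SK (1.88 (SE 0.24)), RSPH1 (1.80), PIERCE1 (1.76) and H2BC21 (1.74). The rises of MT1G and RSPH1 rest mainly on shRNA #5: MT1G stood at 8.39 in shRNA #5, 4.84 in shRNA #2 and 4.65 in scramble, and RSPH1 at 8.20, 5.50 and 5.05. As a description, the median of the ATF4 and unfolded protein response list before Tet was -0.86 for shRNA #5 and -0.95 for shRNA #2, against -0.15 after 3 days of Tet and -0.033 at 4 h. The mean difference before Tet had a list median of -0.90, below each of 10000 random lists matched on size and signal, with the largest values in VLDLR, PSAT1, STC2 (-2.19) and ATF5 (-2.0). The scramble array is assumed to vary like the 2 knockdown arrays. On simulated data this comparison found 4.50% of genes changed 2-fold and 88.8% of those changed 4-fold. Those data held 100 changed genes of each size and independent noise. In the measured data DPY30, the targeted gene, was 5.58-fold lower and did not pass, so the count of 0 does not show that such changes are absent.

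The 2 shRNAs were compared through their differences from scramble across 12198 genes, which are not independent replicates. Before Tet, where both are set against the same scramble array, Pearson's r was 0.595 and Spearman's rho 0.560. Simulated arrays with no knockdown effect and a shared scramble array gave r 0.499, and a covariance of 0.0459 against the measured 0.0934. With no array shared, shRNA #5 before Tet against shRNA #2 gave r 0.249 after 3 days of Tet (rho 0.232) and 0.195 at 4 h (rho 0.178). Within shRNA #2, r was 0.453 between the states before Tet and after 3 days, 0.644 between 3 days and 4 h, and 0.368 between before Tet and 4 h.

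The last comparisons ask whether the responses to Tet and to its removal differed in knockdown cells, since the series title concerns DPY30 and Myc at its targets. Over the 1857 genes changed by Tet removal, the shRNA #2 response was 0.886 times the scramble response by slope, and 1231 genes (66.3%) changed less in shRNA #2 cells. The slope was 0.875 for genes that rose and 0.902 for genes that fell. The response to 3 days of Tet gave a slope of 0.880 over 5807 genes, with 62.8% changing less. These slopes are given without a test. Both use the same 2 arrays of 3 days of Tet, so they are not independent, and a deviation of 1 of these arrays was not examined for them. Some lists went against the slope of the Tet response: the median response to Tet was -1.08 in scramble and -1.96 in shRNA #2 cells for mitosis genes, -0.71 and -0.96 for glycolysis, and -0.45 and -0.61 for oxidative phosphorylation, also without a test. By list, the median removal response of ribosome biogenesis genes was 1.47 in scramble and 0.97 in shRNA #2 cells. The median difference of that list was -0.42, that of classical Myc targets -0.37, of mitochondrial ribosomal protein genes -0.28 and of cholesterol synthesis genes -0.50. The first 3 medians lie below each of 10000 matched random lists, 0.01% of such lists lie as low as the fourth, and all 4 keep their sign under the other 3 normalizations. The random lists were not matched on the response to removal, and their genes are drawn singly, while members of a list can move together. A list that rises in scramble cells lies low in part through the slope below 1 alone, so these ranks are no test. The largest positive list medians of this difference were 0.50 for immediate early genes and 0.44 for p53 targets.

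By gene, 0 passed in limma for a difference in the removal response (302 at an unadjusted p under 0.05, where 610 would come by chance). The largest values were FOS (2.24 (SE 0.40)), SMAD6 (1.97), A4GALT (1.95), EEIG1 (1.84) and MIR181A2HG (1.84) on the higher side. On the lower side were endothelin EDN1 (-2.16 (SE 0.79)), the chemokine receptor CCR2 (-1.93), DCLK2 (-1.91), the cholesterol synthesis gene HMGCS1 (-1.87) and FCRL2 (-1.84), each with adjusted p = 1. For the response to 3 days of Tet 0 genes passed in limma (569 at an unadjusted p under 0.05; smallest adjusted p 0.976). The largest values were INHBE (3.83 (SE 1.2)), IGFBP4 (3.38), the interleukin receptor IL7R (2.79) and ASS1 (2.60). No exact value is given for STC2, next on that side, which was undetected on the scramble array of 3 days. Nor is one given for MT1F, TNS3, MT1G, TYROBP and HECW2 on the lower side, which were undetected on the scramble array before Tet, TNS3 and TYROBP on all 3 arrays before Tet. The knockdown baseline of this contrast is the mean of both shRNAs, and before Tet MT1F (6.66 against 4.64) and MT1G were high in shRNA #5 and not in shRNA #2. INHBE and ASS1 largely restate their difference before Tet with the sign turned. At 3 days scramble and shRNA #2 cells stood at 5.76 and 5.44 for INHBE, and both at 7.59 for ASS1. Their values thus rest on the lone scramble array before Tet (10.48 and 12.28). On simulated data these 2 tests found 2.60% and 0.30% of genes that differ 4-fold, so their counts of 0 leave such differences open.

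**Figure D4:**
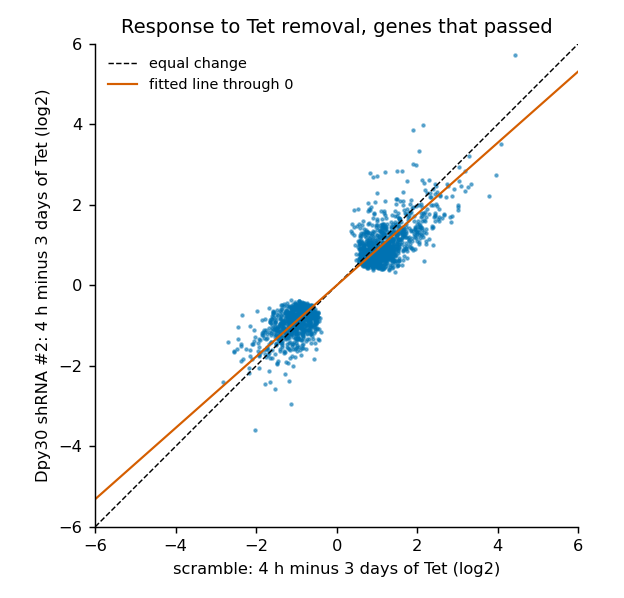
Change from 3 days of Tet to 4 h after its removal (log2) in scramble cells against that in shRNA #2 cells, 1 point for each of the 1857 genes that passed. The fitted line through 0 has a slope of 0.886 and lies below the dashed line of equal change for genes that rose.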

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

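The difference described here was noticed in the list medians and was not tested. Cholesterol synthesis genes moved apart on Tet removal: the median change of the 16 measured members over 4 h was 0.49 in scramble cells and -0.234 in shRNA #2 cells, and it was flagged because the directions are opposite. At 4 h, 15 of the 16 genes lay below scramble in shRNA #2 cells (median -0.64), against 8 of 16 after 3 days of Tet (0.011). The largest differences in response were in HMGCS1 (-1.87, SE 0.36), SQLE (-1.69, SE 0.39) and MSMO1 (-1.37, SE 0.47), each with limma adjusted p = 1. No biological explanation was tested, and each cell of that comparison holds 1 array.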

How the results depend on the processing

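The alternative of equal medians for the list tests was chosen only after the results were seen; the others were planned. For knockdown, the count of 273 genes became 163 after quantile normalization without background correction, 99 with the authors' median-scaled values, 459 with an intensity trend and robust variance, 668 with 6 arrays of scramble and shRNA #2, and 129 in the cell-means fit, and leaving out 1 array gave 0 to 668. Of the 273, all were among the 668, 269 among the 459, 189 among the 561 called without the scramble array before Tet, 135 among the 163, 95 among the 99 and 83 among the 129. The other settings gave 285 to 350, with 212 of the 273 or more among them. The Tet count of 5807 was 3440 to 5634 when 1 array was left out, and the removal count of 1857 was 185 to 2201, with all other settings within 1.5 times of both. Fewer arrays leave fewer degrees of freedom. For knockdown, leaving out any array of 3 days or of 4 h, or the scramble array before Tet, also takes that whole state out of the estimate. Beyond that the cause was not tested. The list tests, 47 called, gave 0 with the correlation estimated, where camera has 3 residual degrees of freedom, and 42 to 50 otherwise. Knockdown before Tet and both differences in response gave 0 genes in each setting that could be fitted. An array without which a contrast of the cell-means fit has no residual degrees of freedom could not be left out. DPY30 averaged 16.7% of scramble in knockdown, and the other DPY30 probe, near background, gave 62.1%. When 1 array was left out, 3 results changed sign: the removal medians of polyamine synthesis (-0.0553 to 0.282) and of ATF4 and unfolded protein response genes (-0.0268 to 0.655), and the removal change of DPY30 (-0.07475 to 0.07347, with 0.03939 without the shRNA #2 array of 4 h), which never passed. Leaving out 1 array left the sign and the outcome, passed or not, unchanged in 85 of 280 comparisons of named knockdown genes. For Tet it did so in 855 of 875 and for removal in 511 of 735. Other settings did so in 267 of 309, 977 of 984 and 804 of 830. These tallies are not all kept calls, since MYC for knockdown and DPY30 for removal had not passed. Slopes of the removal response were 0.862 to 0.914. Signal over background limits dim genes such as CAMP and CD1D.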

Other observations

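The tests of MYC left after Tet, of the lone scramble array and of splits within Tet states were chosen only after the results were seen; the others were planned. Some further list medians are given here as descriptions without a test. tRNA synthetase genes lay lower in knockdown before Tet (median -0.22, 0.09% of matched random lists lie as low), with MARS1 (-0.98), GARS1 (-0.98) and AARS1 (-0.95) as examples that did not pass. After 3 days of Tet their median difference of shRNA #2 from scramble was 0.277, with 13 of 18 genes above 0, and at 4 h it was -0.015. Oxidative phosphorylation genes lay higher in knockdown before Tet, with 49 of 57 above 0 and a median of 0.21 (0.255 for shRNA #5 and 0.114 for shRNA #2). With shRNA #2 the median was 0.0085 after 3 days of Tet and -0.103 at 4 h. For tRNA synthetase and oxidative phosphorylation genes, the differences before Tet rest on the lone scramble array of that state. A deviation of that array cannot be told apart from an effect of knockdown. The median response of MHC genes to 3 days of Tet was 1.64 in scramble and 1.19 in shRNA #2 cells.

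The number of genes changed by knockdown was set against the splits of the 7 arrays that swap labels only within a Tet state. There are 12 of these with the real one, too few for a share under 0.05. The planned count over all 34 splits that could be fitted was replaced by this one, because the other splits leave fewer pairs of arrays within a state to compare. In the planned count too the highest other split gave 94 genes. Of the 12, 1, the real one, gave as many as 273 genes, and the highest other gave 94. The other splits keep the pairs of arrays of 3 days and of 4 h, with the sign turned in some. The split with 94 genes turns both, so it is not free of the knockdown difference and is no measure of chance. For the number of lists, 8 of the 12 called as many as the real 8 (adjusted within 1 comparison), and the highest other called 14.

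The median of the mitosis list was -0.647 with knockdown. Of its 32 genes 3 passed, and the list was not called with an estimated correlation (adjusted p = 0.41). Background correction and scaling are argued against, since the median stayed at or below -0.474 under the other 3 normalizations. So is the deviation of 1 array, since it stayed at or below -0.458 whichever was left out. Of the 12 splits within Tet states, too few for a share under 0.05, 1, the real one, gave a median as far from 0. The highest other gave 0.625, and it holds both later pairs of arrays with the sign turned, so it is no measure of chance. Among the splits not kept within states, 1.2 and -1.2 lay further from 0, each resting on the 2 arrays of 3 days alone. So did 0.813 and -0.813, each resting on the 2 arrays of 4 h alone. An effect of knockdown and other differences between the cultures stay open, as untested.

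Slopes of the responses to Tet and to its removal were below 1 in shRNA #2 cells relative to scramble, without a test. Both slopes share the 2 arrays of 3 days, and a deviation of 1 of these was not examined. Scaling is argued against, since the slope of the removal response was at most 0.884 under the other 3 normalizations. A candidate explanation is that more MYC was left after Tet in those cells, where MYC stood at 165% of scramble (160% with its second probe). With the authors' median-scaled values these were 146% and 143%. At 4 h the 2 probes gave 111% and 130%. The 638 genes that fell with Tet and rose on removal lay above scramble after 3 days by a median of 0.286. Their interquartile range was 0.065 to 0.527, and at 4 h their median was -0.039. Before Tet their median was already 0.0945, with 66% of genes higher. The 589 genes that rose with Tet and fell on removal had a median of -0.128 after 3 days (interquartile range -0.407 to 0.159). Other values do not follow from more MYC: in shRNA #2 cells the median of mitosis genes, which fall with Tet, was -1.20 against scramble after 3 days (31 of 32 lower). At 4 h that of ribosome biogenesis genes was -0.195 (43 of 53 lower) and that of mitochondrial ribosomal protein genes -0.118 (50 of 67 lower). These are single pairs of arrays, which leave more MYC open as part of the difference. Both this and a weaker response to Myc with less DPY30 stay open and cannot be told apart, because the higher MYC is itself in the only knockdown array of that state.

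The median of the ATF4 and unfolded protein response list was negative for both shRNAs before Tet, a description without a test. Scaling is argued against, since the list median nearest 0 over both shRNAs and the other 3 normalizations was -0.764. A deviation of the lone scramble array before Tet could give the same pattern and cannot be told apart from an effect of knockdown. The list differed by a median of 0.158 between the shRNAs, which either would allow, and no second scramble array before Tet exists to decide it.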
